A study of Mus musculus with 8 samples.

How the data were processed

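Genomic DNA of mouse bone-marrow-derived myeloid cells was sequenced at the target sites of 2 guide RNAs, 1 against Cebpb and 1 against Itgam. Per the labels, marrow cells of a Cas9-GFP transgenic strain were grown with GM-CSF, infected on day 2 with a mix of 2 lentiviruses, and sorted in bulk at about 4000 cells per population. The Itgam guide travelled with BFP and the Cebpb guide with mCherry, both fluorescent proteins. Libraries were made with primers on either side of the target and read on a MiSeq.

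The sample titles name 4 populations (DN, SP-Cebpb, SP-Itgam and DP) and 2 amplicons, which gave 8 libraries, 1 per population and amplicon, with no replicates. The labels do not spell out DN, DP and SP; in sorting by 2 markers they usually stand for cells with neither marker, with both, and with 1 of them. The selection marker label of all 8 samples reads GFP+BFP+CD11c+. As written, it would make every population, DN and SP-Cebpb included, positive for the reporter of the Itgam guide, which goes against that reading of DN and SP-Cebpb. What the Itgam shares of these populations stand for therefore rests on the titles. The labels also disagree on stimulation: the protocol gives lipopolysaccharide for 4 hours on day 7, and the sample attribute says unstimulated. The library protocol in the labels describes single-cell RNA libraries, so the amplicon protocol itself was not given in the sources used here.

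Each deposited file holds, per line, a raw read count and an alignment string, with no normalization. A string gives the lengths of matched, inserted, deleted and clipped stretches, but no bases, start position or strand. Per the submitters' processing notes, bcl2fastq 2.15.0.4 and the mouse build mm9 were used; the aligner, any read filter and the guide and primer sequences were not given in the sources used here. Substitutions could not be seen, and no genomic coordinates are given, since the strings carry none and no mm9 sequence was used here.

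Positions were counted in reference bases from the last base of each string. This end was chosen after the data had been examined, because deletions lined up on it. In the SP-Cebpb library of the Cebpb amplicon, 84.1% of reads with a single deletion of 10 or more bases ran across the peak when counted from the end. Counted from the start, 2.00% did. For SP-Itgam at the Itgam amplicon these shares were 91.9% and 3.47%. At Cebpb the share counted from the end was 59.5% in SP-Itgam and 14.1% in DN, where 1 deletion of 17 bases far from the peak, at bases 144 to 160, was the commonest long deletion. Strings that start at one fixed primer at their end would give this picture.

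The cut region was placed at the base with the largest excess of indel reads in the library of the amplicon's own guide over DN: base 38 for Cebpb and base 32 for Itgam. A read was called edited when an insertion or deletion touched the 10 bases on either side of that base. Events inside this window defined the merged allele, whatever clips or other indels the string held. A frameshift was a net length change in the window that is not a multiple of 3; whether the whole window lies in coding sequence was not checked.

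Shares have 95% Wilson intervals and differences Newcombe intervals. Pairs of libraries of 1 amplicon were compared by two-sided Fisher's exact tests on reads, with Benjamini-Hochberg adjustment over 12 pairs, also for the frameshift share. Edit classes were compared by the total variation distance, in percentage points, with a permutation test of 100000 resamples. These tests compare libraries, not conditions. Reads are PCR copies without molecular identifiers, so read-based intervals cover counting error only and are too narrow for cells. Intervals were therefore also made from 4000 molecules, the approximate number of sorted cells, and from estimated templates. The template number was the total reads divided by the median reads of merged alleles seen in that library with at least 20 reads and in each other library of the amplicon with at most 3. It came to between 629 and 1019 per library and assumes that such an allele began as 1 molecule. The intervals also take every template as giving equal reads. Such alleles ran from 29 to 343 reads in SP-Cebpb at Cebpb and from 25 to 670 in SP-Itgam at Itgam. Where amplification was uneven, intervals from estimated templates are too narrow.

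Total reads ranged from 56251 to 100573 per library, 646698 in all. A count of 0 allowed at most 0.00298% to 0.00533% of reads, a limit that holds for reads and not for cells. The alleles named were fixed by a rule before the data were examined: the 5 edited strings with the most reads in the library of the amplicon's own guide and in DP, and the top 2 in DN and in the other guide's library, with at least 3 reads. Other alleles were chosen after their values were seen and are marked so. Alternatives covered the window, read minimums, background subtraction, the commonest allele, clipped reads, the end from which positions were counted and the effective number of molecules. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The calls were tested on 4 simulated libraries, where edited shares, frameshift shares and cut bases were recovered with differences of 0. Every simulated edit touched the cut base and no random read errors were added. This checks the code, and not the choice of end or window. The distance test called 6% of 200 unchanged simulated pairs at 0.05. Their reads were drawn independently, so this rate does not cover reads that are PCR copies.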

Results

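Amplicons across the Cebpb and Itgam guide sites were read in 4 sorted populations of infected myeloid cells, in a study that joined pooled CRISPR screening to single-cell RNA sequencing. Cebpb encodes C/EBP beta, a transcription factor of myeloid cells, and Itgam encodes CD11b, the alpha chain of a myeloid integrin. Cas9 cuts at the guide's target, and imprecise repair leaves short insertions or deletions (indels). The comparison asks how much of each locus was edited in the population named for its guide, in DP, in the population named for the other guide and in DN. At the Cebpb amplicon, DN had 65184 reads, SP-Cebpb 56251, SP-Itgam 70503 and DP 74630. At the Itgam amplicon, DN had 91715 reads, SP-Cebpb 89259, SP-Itgam 98583 and DP 100573. There was 1 library per population and amplicon, so no difference below has a replicate check.

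Indels in excess of DN peaked at 1 base per amplicon, and reads of all 4 populations carried indels there. At base 38 from the end of the Cebpb strings, 48.3% of SP-Cebpb reads carried an indel, against 35.2% in DP, 15.4% in SP-Itgam and 3.65% in DN. At base 32 of the Itgam strings, the share was 69.0% in SP-Itgam, 52.8% in DP, 14.3% in SP-Cebpb and 4.25% in DN. The largest excess fell on the same bases when the other guide's library took the place of DN.

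**Figure D1:**
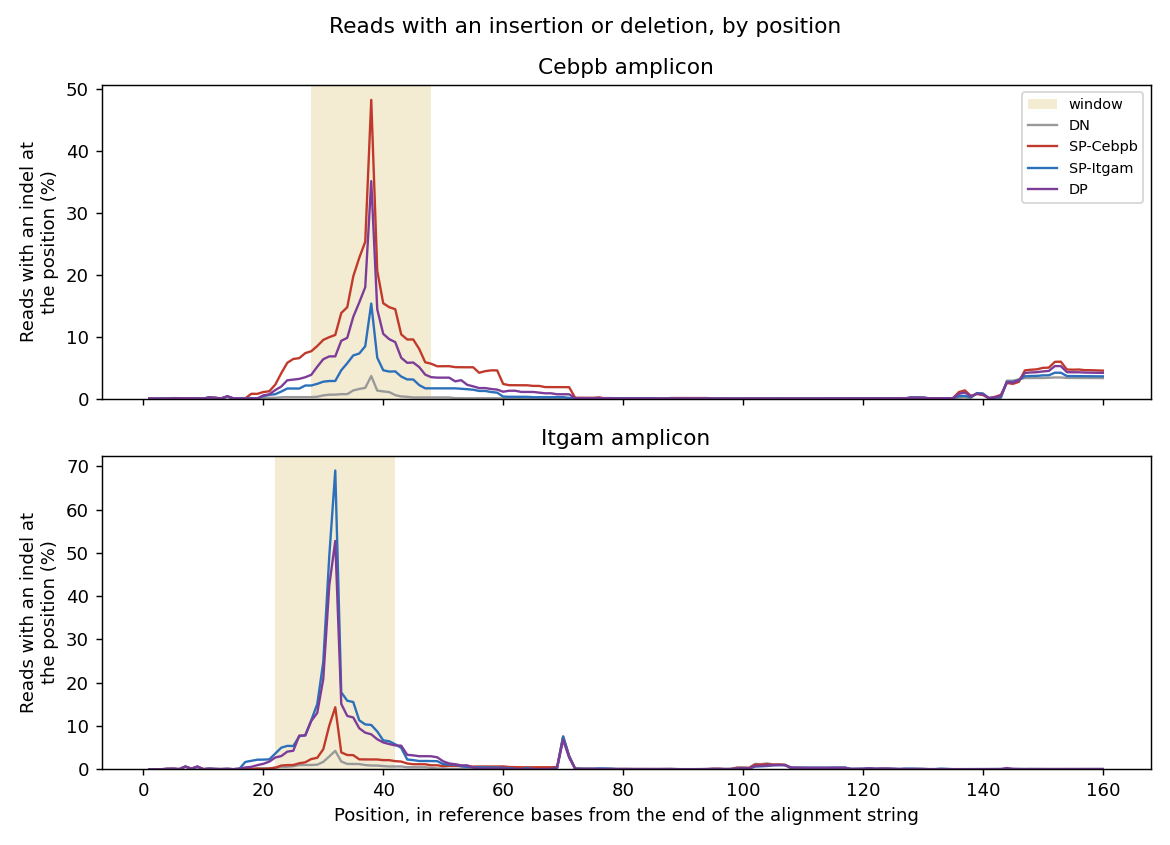
Percentage of reads with an inserted or deleted base at each position, in reference bases from the end of the alignment string, for the Cebpb amplicon (top) and the Itgam amplicon (bottom), 1 line per sorted population. All 4 Cebpb lines are highest at base 38 and the Itgam lines of SP-Cebpb, SP-Itgam and DP at base 32, each inside the shaded window of 10 bases on either side; the Itgam line of DN is highest at base 70 (7.46%, against 4.25% at base 32), where the other populations have 6.79% to 7.60%, and the Cebpb lines rise again at bases 144 to 160, where a 17-base deletion occurs in 2.14% to 2.79% of reads.

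Editing of Cebpb was highest in SP-Cebpb, lower in DP, much lower in SP-Itgam and lowest in DN. In SP-Cebpb, 53.7% of reads were edited (95% Wilson interval 53.3 to 54.1; 50.2 to 57.2 with estimated templates). In DP the share was 38.2% (37.9 to 38.6; 34.8 to 41.8 with estimated templates). SP-Itgam, named for the other guide, had 16.5% (16.2 to 16.7; 14.3 to 18.9). DN, the lowest, had 4.06% (3.91 to 4.22; 3.01 to 5.46). SP-Cebpb lay 49.6 percentage points above DN (Newcombe interval 49.2 to 50.1) and DP 34.2 points above it (33.8 to 34.5). SP-Itgam was still 12.4 points above DN (12.1 to 12.7).

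Editing of Itgam had the mirrored order and reached higher levels. SP-Itgam had 73.1% edited reads (72.8 to 73.4; 69.7 to 76.3 with estimated templates) and DP 55.3% (55.0 to 55.6; 51.4 to 59.1). SP-Cebpb, here the population of the other guide, had 15.1% (14.8 to 15.3; 12.9 to 17.5) and DN 4.68% (4.55 to 4.82; 3.52 to 6.21). SP-Itgam lay 68.4 points above DN (68.1 to 68.7), DP 50.6 points (50.3 to 50.9) and SP-Cebpb 10.4 points (10.1 to 10.7). All 12 pairs of libraries within an amplicon differed by Fisher's exact test, with an adjusted p of 1e-300 on reads, the smallest value written. With estimated templates all 12 still differed, with a largest adjusted p of 1.45e-09 by Fisher's exact test. The low DN shares changed little with windows of 3 and 20 bases, to 4.03% and 4.08% at Cebpb and 4.61% and 4.91% at Itgam. They rose when indels anywhere in the string were counted: DN had 8.93% at Cebpb and 15.4% at Itgam, and SP-Cebpb had 24.9% at Itgam. Reads with indels only beyond the window, farther from the end, made up 4.17% of DN reads at Cebpb and 9.25% at Itgam.

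**Figure D2:**
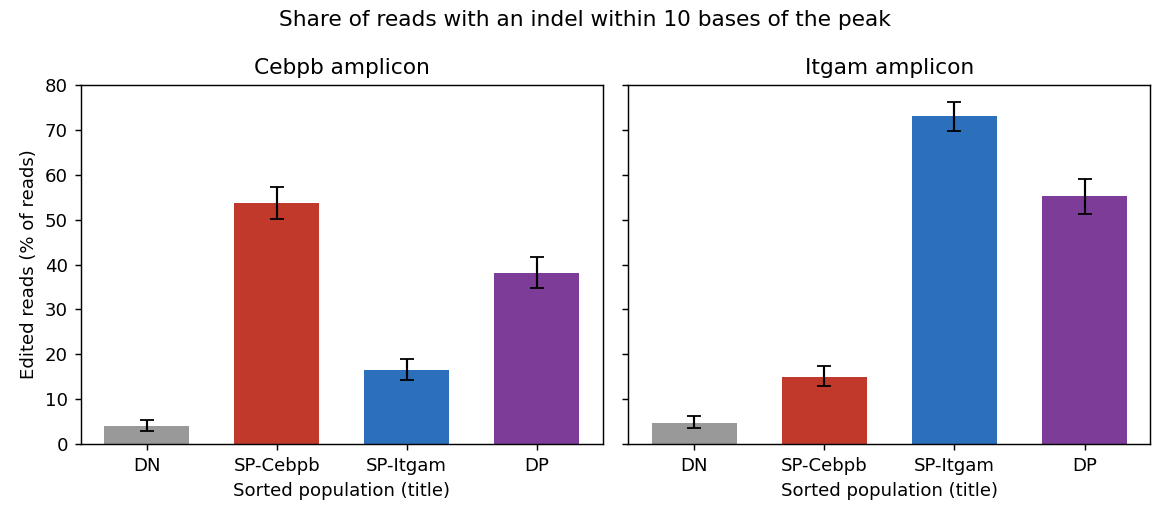
Percentage of reads with an indel within 10 bases of the peak, for the Cebpb amplicon (left) and the Itgam amplicon (right), 1 bar per sorted population and 1 library per bar. Error bars are 95% Wilson intervals computed with the estimated number of templates; Cebpb editing reaches 53.7% in SP-Cebpb and Itgam editing 73.1% in SP-Itgam, while both lie below 5% in DN.

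Both genes were edited less in DP than in the population named for their own guide alone. For Cebpb the gap was 15.5 points (14.9 to 16.0; 10.5 to 20.4 with estimated templates), a ratio of SP-Cebpb to DP of 1.40 (1.39 to 1.42). For Itgam the gap was 17.8 points (17.4 to 18.2; 12.7 to 22.8 with estimated templates), a ratio of SP-Itgam to DP of 1.32 (1.31 to 1.33). With the DN share taken off, the ratios were 1.45 and 1.35. Since DP held 38.2% edited Cebpb reads and 55.3% edited Itgam reads in separate amplicons, the share of cells edited at both loci cannot be read from these data.

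Most edited reads at both loci had a net length change that is not a multiple of 3, here called a frameshift, which breaks the reading frame where the site lies in coding sequence. It was found in 89.4% of edited SP-Cebpb reads (89.0 to 89.7) and 89.0% of edited DP reads (88.6 to 89.3) at Cebpb. At Itgam it was found in 79.4% of edited SP-Itgam reads (79.1 to 79.6) and 76.3% of edited DP reads (75.9 to 76.6). As a share of all reads, frameshifts made up 48.0% at Cebpb in SP-Cebpb, 34.0% in DP and 3.55% in DN, and 58.0% at Itgam in SP-Itgam, 42.2% in DP and 3.42% in DN. The Cebpb difference between SP-Cebpb and DP, 0.390 points (-0.113 to 0.894), did not pass the test (Fisher's exact p = 0.130, adjusted 0.142). The Itgam difference, 3.06 points (2.60 to 3.52), passed on reads (Fisher's exact p = 5.78e-39, adjusted 6.94e-38), but with estimated templates its interval ran from -2.54 to 8.83 and Fisher's exact p was 0.311.

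Edited reads at both loci held deletions far more often than insertions. Deletions alone made up 96.0% of edited Cebpb reads in SP-Cebpb (95.8 to 96.3) and 96.8% in DP (96.5 to 96.9), and 96.8% of edited Itgam reads in SP-Itgam (96.7 to 96.9) and 97.6% in DP (97.4 to 97.7). Single 1-base deletions led at Cebpb, with 41.6% of edited SP-Cebpb reads, while 2-base deletions led at Itgam, with 35.3% of edited SP-Itgam reads. Single deletions of 20 or more bases made up 14.0% of edited Cebpb reads in SP-Cebpb and 11.5% in DP, and 5.42% of edited Itgam reads in SP-Itgam and 7.55% in DP. Insertions of 1 base reached 3.53% of edited Cebpb reads in SP-Cebpb, 2.72% in DP and 0.931% in SP-Itgam, and 0.0378%, a single read, in DN. At Itgam the order was the opposite, with 9.92% of edited reads in DN, 1.52% in SP-Cebpb, 0.295% in DP and 0.107% in SP-Itgam. Of the 426 such reads in DN, 400 held 1 allele, so the DN share may rest on few molecules. The class shares of SP and DP differed by 0.813 points at Cebpb and 0.952 points at Itgam, each with a permutation p of 1e-05, the smallest these permutations can give (adjusted 1.09e-05). With estimated templates the permutation p was 0.681 and 0.584.

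A few alleles recurred in every population and carried most of the editing. At Cebpb, the 1-base deletion at base 38 was the leading allele in all 4 libraries, with 41.2% of edited reads in SP-Cebpb (40.6 to 41.8), 42.0% in DP (41.4 to 42.5), 42.0% in SP-Itgam (41.1 to 42.9) and 44.5% in DN (42.6 to 46.4). Its share of all reads went from 1.81% in DN to 22.1% in SP-Cebpb. The 2-base deletion of bases 37 to 38 held 9.01% of edited reads in SP-Cebpb, 9.90% in DP, 10.5% in SP-Itgam and 7.85% in DN. The 2-base deletion of bases 35 to 36 held 5.21%, 5.18%, 3.95% and 6.34% in the same order. The alignment wrote the leading deletion in several ways, with 0, 1 or 3 bases clipped at the start of the string, and these strings filled 3 of the top 5 places in SP-Cebpb and DP.

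At Itgam, the leading allele in all 4 libraries was the 2-base deletion of bases 31 to 32. It held 33.3% of edited reads in SP-Itgam (32.9 to 33.6), 35.7% in DP (35.3 to 36.1), 33.0% in SP-Cebpb (32.2 to 33.8) and 24.3% in DN (23.0 to 25.6). The 1-base deletion at base 32 held 25.1% in SP-Itgam and 26.0% in SP-Cebpb, but 17.6% in DP and 14.6% in DN. The 3-base deletion of bases 30 to 32 held 10.1% in SP-Itgam, 13.2% in DP, 8.99% in SP-Cebpb and 11.2% in DN. The 8-base deletion of bases 28 to 35 held 2.88%, 3.39% and 3.35% in SP-Itgam, DP and SP-Cebpb, and 1 read, 0.0233% of edited reads, in DN. The 4-base deletion of bases 29 to 32 held 2.26% in SP-Itgam, 1.82% in DP, 1.03% in SP-Cebpb and 0.0931% in DN. The 18-base deletion of bases 26 to 43 held 2.99% in DP, 1.25% in SP-Itgam and 0.906% in SP-Cebpb, and 0 of 91715 reads in DN. That allows up to 0.00327% of reads, but the limit for cells is wider, since DN had an estimated 960 templates here. Neither this absence nor the 1 read of the 8-base deletion shows that DN cells lacked these alleles.

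**Figure D3:**
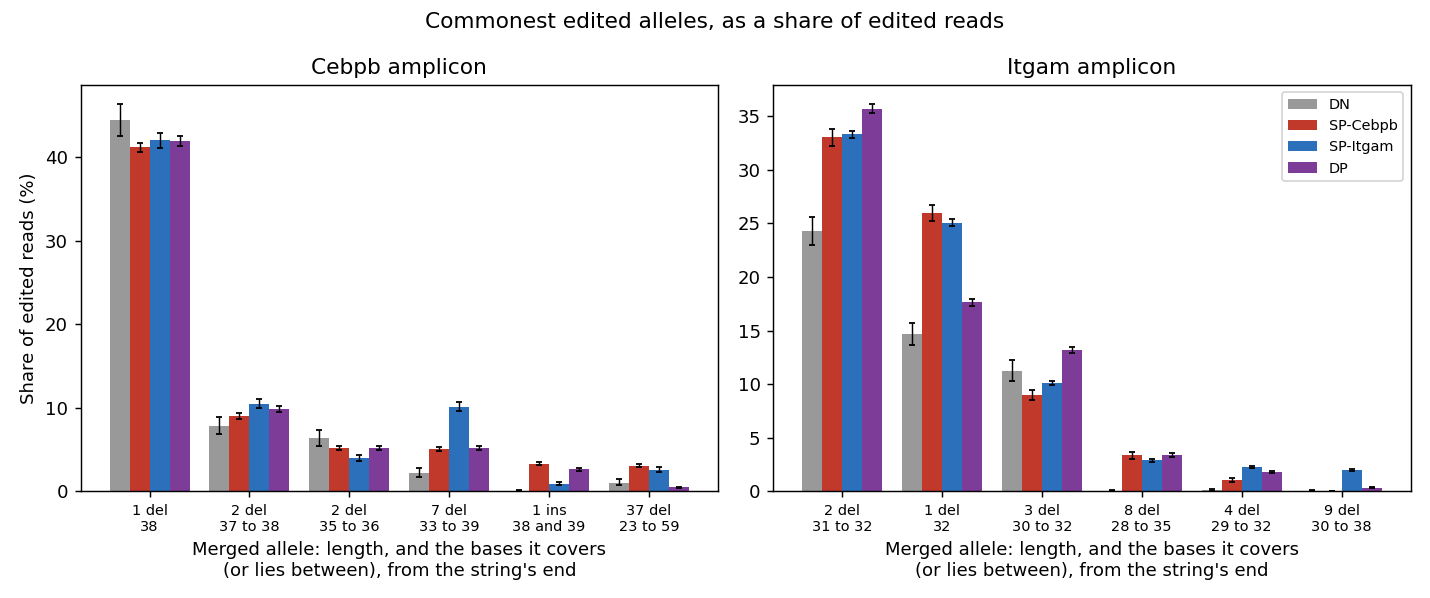
Share of edited reads (percent) held by the 6 commonest merged alleles of the library of the amplicon's own guide, for Cebpb (left) and Itgam (right), 1 bar per sorted population; each label gives the allele's length (del, deletion; ins, insertion) and its bases from the end of the string, and error bars are 95% Wilson intervals over reads. The 1-base Cebpb deletion at base 38 holds 41.2% to 44.5% in all 4 populations, while the 1-base Itgam deletion at base 32 ranges from 14.6% in DN to 26.0% in SP-Cebpb.

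DP and the population of the same guide shared most of their edited reads but a minority of their distinct strings when every string was counted. At Cebpb, 474 of 2338 edited strings occurred in both SP-Cebpb and DP, and they held 86.6% of edited SP-Cebpb reads and 82.9% of edited DP reads. At Itgam, 705 of 3846 strings occurred in both SP-Itgam and DP and held 90.4% and 89.7% of their edited reads. Across shared strings the Spearman correlation of read counts was 0.75 at Cebpb and 0.66 at Itgam. Across all strings seen in either library it was -0.19 and -0.25, where a string absent from 1 library counts as 0. With strings of at least 3 reads in either library, this correlation turned to 0.054 and 0.042. In that setting 317 of 578 strings were shared at Cebpb and 439 of 812 at Itgam. With strings merged to alleles and no minimum, 98 of 289 and 141 of 443 were shared. These correlations are across alleles, which are not independent replicates, and the values over shared strings were added after the data had been examined.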

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

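The 3 patterns weighed here were tested only after their values had been seen, so every test of an explanation in this part was chosen after the result.

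Reads clipped inside the cut region were not counted as edited, and they stood above DN in the library of each amplicon's own guide. Reads with a clip of 10 or more bases ending in the window, and no indel there, made up 1.60% of SP-Cebpb reads at Cebpb (DN 0.0798%) and 1.53% of SP-Itgam reads at Itgam (DN 0.0829%). The effects also differed between the amplicons, tested as differences of log2 odds ratios, Itgam minus Cebpb. The population of the own guide against DN differed by 1.01 (0.31 to 1.71 with estimated templates), and DP against DN by 0.78 (0.09 to 1.48). The own guide's population against DP differed by 0.23 and the other guide's population against DN by -0.36. Both of these passed on reads (0.19 to 0.27 and -0.44 to -0.28) but not with estimated templates (-0.21 to 0.67 and -1.08 to 0.35).

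DN held edited reads, 4.06% at Cebpb and 4.68% at Itgam. Reads carried over after amplification would bring each source's alleles in proportion, and the source alleles scarcest in DN allowed at most 29.3% of its edited reads in the higher of both amplicons, a bound that covers counting error of reads only. Deletions of 2 or more bases starting in the window were 0.565 times as frequent as in the highest other window of equal width at Cebpb and 2.23 times at Itgam, and without the 1 commonest deletion outside the cut window (17 bases at Cebpb, 4 bases at Itgam) the ratios were 2.72 and 5.52, so these values decide nothing on error. An error of equal rate in every library allowed 77.3% of the edited DN reads at Cebpb and 70.3% at Itgam from reads. With estimated templates it allowed 100% at both. DN had few edited templates, and bounds on counts divided to templates are wide, so a lower value was unlikely. That value therefore decides nothing, and error stays open. Cells that carry the guide without falling in a positive gate, and impurity of the sort, cannot be told apart either: DN had 9 alleles of its own with 20 or more reads, which either may give, and the 1 selection marker label shared by all 8 samples does not tell the gates apart.

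The population of the other guide was also edited, at 16.5% for Cebpb in SP-Itgam and 15.1% for Itgam in SP-Cebpb. Carry-over of reads after amplification allowed at most 31.4% of these edited reads in the higher of both amplicons, counting DN as a source of up to all reads, a ceiling set after the first values were seen. An error of equal rate in every library allowed at most 65.9% of them at Cebpb and 68.4% at Itgam with estimated templates, which argues against it as the whole source but not as a part. The window held 1.86 times the deletions of the highest other window at Cebpb (5.52 without the 17-base deletion), which decides nothing, and 7.81 times at Itgam, which argues against error there. Both libraries together had 21 alleles of their own with 20 or more reads, so a candidate explanation is cells that received the guide but showed its reporter below the gate, or mis-sorted cells, and these cannot be told apart.

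DP was edited less than the population of the same guide alone at both loci. Sampling of few templates is argued against, since the lower bound of the gap with estimated templates was 10.5 points at Cebpb, the smaller of both. That bound leaves out uneven amplification of templates. Leaving out the commonest merged allele of each library, from edited and total reads alike, kept at least 91.3% of the gap. Total reads shrank as well, so part of the gap would remain even if only that allele differed, and this value decides nothing. Among all reads, the 1-base Cebpb deletion at base 38 held 22.1% in SP-Cebpb and 16.0% in DP. The 2-base Itgam deletion of bases 31 to 32, the commonest there, held 24.3% in SP-Itgam and 19.7% in DP. The 1-base Itgam deletion at base 32, which was not left out, held 18.3% in SP-Itgam and 9.74% in DP. Single alleles thus carried part of the gap. Counting indels anywhere and clipped reads kept at least 96.1%. The shares of these alleles among all reads differed by less than the gap, which argues against 1 dominant allele as the whole cause. The 96.1% argues against indels beyond the window or clipped reads as the whole cause. Deletions that remove a primer or reach past the read were not tested. Unedited cells in the DP sort and less cutting per cell when both guides are present cannot be told apart: both predict a lower share with similar alleles. The allele shares of edited reads in DP and the own guide's population differed by 21.3 points at Cebpb and 23.7 at Itgam. Those of SP-Cebpb and SP-Itgam differed by 28.8 and 22.5 points. No limit for similar alleles was set before the values were seen, so these distances decide nothing.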

How the results depend on the processing

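All 12 differences between libraries kept their direction and stayed past the threshold in each of 132 recomputed values, with a largest adjusted p of 1.45e-09 by Fisher's exact test. Counting positions from the start, adding clipped reads and using estimated templates were chosen after the data had been examined. Libraries are given in the order DN, SP-Cebpb, SP-Itgam, DP, and values inside the main interval are left out.

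At Cebpb, the edited share was 8.93%, 56.1%, 20.7% and 41.5% with indels anywhere, 3.48%, 52.8%, 15.5% and 36.9% with strings of at least 10 reads, and 3.21%, 48.9%, 13.6% and 33.3% without the commonest edited string. Counted from the start it was 3.87%, 46.4%, 14.4% and 34.8% in read bases and 3.53%, 43.1%, 13.3% and 32.5% in reference bases. Strings of at least 2 reads gave 3.82% in DN, 16.1% in SP-Itgam and 37.7% in DP, and a window of 3 bases 53.3% in SP-Cebpb. Clipped reads raised SP-Cebpb, SP-Itgam and DP to 55.3%, 16.8% and 39.5%. Less the DN share, these were 49.6%, 12.4% and 34.2%; less the SP-Itgam share, SP-Cebpb and DP were 37.2% and 21.8%.

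At Itgam, the edited share was 15.4%, 24.9%, 76.8% and 60.3% with indels anywhere and 3.80%, 11.4%, 66.2% and 46.4% without the commonest edited string. Counted from the start, DN, SP-Itgam and DP had 4.48%, 70.9% and 54.1% in read bases and 4.48%, 70.8% and 54.0% in reference bases. Strings of at least 10 reads gave 4.12% in DN, 14.2% in SP-Cebpb and 54.7% in DP, and those of at least 2 reads 4.39% in DN and 14.7% in SP-Cebpb. A window of 20 bases gave 4.91% in DN and 15.4% in SP-Cebpb, and one of 3 bases 72.7% in SP-Itgam. Clipped reads raised SP-Cebpb, SP-Itgam and DP to 15.5%, 74.6% and 55.8%. Less the DN share, these were 10.4%, 68.4% and 50.6%; less the SP-Cebpb share, SP-Itgam and DP were 58.0% and 40.2%.

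The frameshift difference between SP-Cebpb and DP passed Fisher's exact test, without adjustment, with strings of at least 2 reads (0.565 points, p = 0.0287), at least 10 reads (0.713, p = 0.00636) and without the commonest string (0.771, p = 0.0132). It did not with estimated templates (exact p = 0.901). With each allele counted once it turned to -5.70 points at Cebpb and -2.49 at Itgam, neither past the threshold. The Itgam difference of 3.06 points was lost with estimated templates. The class distance was lost with each allele counted once (3.23 points at Cebpb, 2.67 at Itgam) and with estimated templates (0.915 and 1.13), where fewer units are tested. Frameshift shares of single libraries ran from 66.1% to 90.1% weighted by reads and from 63.6% to 76.3% with each allele counted once. In the order DN, SP-Cebpb, SP-Itgam, DP, 1-base insertions at Itgam made up 22.3%, 11.6%, 1.28% and 2.34% with indels anywhere. With each allele counted once they made up 7.45%, 4.07%, 2.03% and 3.82%. At Cebpb these shares were 0.996%, 3.22%, 1.08% and 2.51%, and 1.52%, 4.48%, 2.78% and 5.91%.

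Shared alleles held 89.2% of SP-Cebpb and 85.5% of DP edited reads at Cebpb with at least 3 reads, and 91.5% and 89.8% when merged. At Itgam these were 92.6% and 92.0%, and 93.4% and 93.9%; with equal edited reads the DP share was 89.2%. The Spearman correlation over strings in either library turned positive with at least 3 reads (0.054 at Cebpb, 0.042 at Itgam) and when merged (0.017 and 0.033), by construction, as fewer rare strings enter. Except where stated, the cause was not tested. Counting substitutions and using another reference sequence were not run, since the strings hold no bases. Deletions that remove a primer or reach past the read are missed at any depth. No analysis paired by replicate was possible because there is 1 library per population and amplicon.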

Other observations

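The alleles and measures in this part were chosen after the data had been examined, and none of these differences was tested. DN held minor Itgam alleles that were scarcer elsewhere. A 1-base insertion between bases 32 and 33 held 9.31% of edited DN reads (8.48 to 10.2), against 1.45% in SP-Cebpb, 0.270% in DP and 0.0444% in SP-Itgam. The interval covers counting error of reads only. Alleles of its own in DN had a median of 95.5 reads here, so the 400 DN reads of this insertion may come from few molecules. The 5-base deletion of bases 32 to 36 had 166 reads in DN, 1 in DP and 0 in both other libraries. It is an allele of DN's own, which the template estimate takes as 1 molecule. At Cebpb, a 7-base deletion of bases 33 to 39 held 10.1% of edited SP-Itgam reads, 5.11% in SP-Cebpb, 5.16% in DP and 2.19% in DN. A 37-base deletion of bases 23 to 59 held 3.09% of edited reads in SP-Cebpb, 2.57% in SP-Itgam, 1.02% in DN and 0.463% in DP.

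Merged alleles with at least 20 reads in 1 library and at most 3 in each other library of the amplicon numbered 138, with a median of 101.5 reads. Few had 10 to 39 reads, in bins of unequal width: of the alleles with at most 3 reads in each other library, 68 had 4 to 9 reads, 11 had 10 to 19, 12 had 20 to 39, 55 had 40 to 99 and 71 had 100 or more. Alleles of 1 to 3 reads are not in this list. They numbered from 23 in DN at Cebpb to 151 in SP-Itgam at Itgam.

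Indels of 1 base at base 70 of the Itgam strings, outside the window, had similar shares in all 4 populations. They occurred in 7.00% of unedited reads in DN, 6.95% in SP-Cebpb, 6.21% in SP-Itgam and 6.53% in DP, and in 6.70%, 6.72%, 7.52% and 6.28% of edited reads. At Cebpb, a 17-base deletion of bases 144 to 160 lay outside the window in 2.79% of DN reads, 2.14% of SP-Cebpb reads, 2.56% of SP-Itgam reads and 2.37% of DP reads. It was found in 2.80%, 2.46%, 2.67% and 2.64% of unedited reads and in 2.57%, 1.87%, 2.03% and 1.94% of edited reads. A 45-base deletion of bases 147 to 191 occurred mostly with an edit, in 3.40%, 3.33%, 3.34% and 3.07% of edited reads against 0.0544%, 0.0537%, 0.0475% and 0.0477% of unedited reads.

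At Cebpb, 37.7% to 41.1% of edited reads were clipped at the start of the string, against 3.74% to 5.82% of unedited reads. At Itgam these shares were 4.52% to 7.10% and 6.43% to 8.10%.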
